A study of Stylophora pistillata with 14 samples.

How the data were processed

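RNA from Stylophora pistillata at 24, 28, 32 and 34 °C was measured on 14 dual-colour custom oligonucleotide arrays. Per the labels' protocols, 200 ng of total RNA with spike-in controls was labelled with Cy3 or Cy5 in each reaction. Per the file headers, the deposited scanner files hold spot and local background intensity for both channels, read by Agilent Feature Extraction 9.5.1.1, together with processed intensity that was background-subtracted and dye-normalized within the array, and the log10 ratio of Cy5 over Cy3. The submitters' processing notes also name Partek, whose role is not given in the sources used here. The authors' deposited series values have no stated scale, and were read as signed fold changes because none lay between -1 and 1, then turned to log2. What they were centred on stays unknown. Against each array's ratio of processed signals, |r| was 0.89 to 0.99, and the 3 columns of the 32 °C biological arrays ran opposite to Cy5 over Cy3 and were turned. Of its 14617 names 14559 matched the arrays. Column medians (log2) were 0.0090, -0.029 and -0.013 for the 28 °C replicates in order, 0.027, 0.040 and 0.091 for 32 °C, -0.0058, 0.052 and 0.0091 for 34 °C, 0.023 and -0.0047 for the technical 34 °C against 24 °C arrays, and -0.053, -0.081 and 0.068 for the technical arrays of 32 °C against 28 °C, 34 °C against 28 °C and 34 °C against 32 °C.

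Mean spot intensities were corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with statmod 1.5.0 and data.table (1.17.8). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Control spots and spots marked as outliers by the scanner software's flags, per the file headers, were left out, and spots of a name were averaged. Of 14560 names, 13662 were kept because at least 3 array channels of at least 1 temperature were well above background, 8375 of them with a database entry name, and 6962 were well above background in every channel. The suffix of an entry name is the species of the database entry, not the source of the transcript. The fit had coefficients for 28, 32 and 34 °C against pooled 24 °C RNA and for dye, with 10 residual and 3.7 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg within each contrast at 0.05, and contrasts of heated temperatures came from the same model. The dye coefficient passed for 0 probes in limma, with 2096 at an unadjusted p under 0.05. Because the fit also uses the technical arrays and the dye coefficient, a fitted value can differ from the mean of the 3 biological arrays. The 32 °C replicate 1 array is described with control set C1 while its title gives C2, and C2 was used.

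Lists of genes for 25 topics were fixed before the data were examined, and 24 had at least 5 measured members. Their gene symbols were translated to entry names after the names on the arrays were seen and before any contrast was fitted. Lists were tested with camera on moderated statistics with a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether members move on balance one way. The list of fluorescent proteins had 1 measured member and was not tested.

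Before the data were examined, the rule for named genes took, for each temperature against 24 °C, the 10 largest rises and 10 largest falls among named genes past the threshold with 3 of 3 biological arrays in the fitted direction, up to 4 members with the smallest adjusted p from each list that passed or had at least 2 members past the threshold, and GRP78, endoplasmin, HSP60, a cytosolic HSP70 and HSP90, catalase, superoxide dismutase and ferritin in every comparison. It named 58, 114 and 111 genes at 28, 32 and 34 °C. Of these 49, 60 and 60 are printed with their errors, by a second rule made after the values were seen: the 5 largest rises and falls, up to 4 list members at 28 °C and 2 at 32 and 34 °C, and the genes named in every comparison. Rule genes that passed in opposite directions at 32 and 34 °C, or whose values reversed in a setting, are printed as well. Counts of calls lost cover every gene of the first rule. At 28 °C 2 printed symbiont sequences are given by value without their numbered names. Genes followed beyond the rule were chosen after their values were seen, and so were the probes named HSP90 and HSP74.

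The fits were tested on simulated data. With the real design, a dye effect and 13662 probes, they recovered 14.9%, 71.6% and 95.5% of log2 changes of 0.5, 1 and 2 at 28 °C, 32.8%, 88.1% and 98.5% at 32 °C and 29.9%, 82.1% and 97% at 34 °C. False calls made up 4.72%, 2.67% and 4.14% of calls, which may not hold with shared or differing extracts. The alternatives were no background subtraction, the scanner software's processed signals, median centring, Aquantile, other filters on dim probes, no dye term, the 24 °C extracts kept apart, the 9 biological arrays alone, averaged technical arrays, replicate and slide blocks, a separate-channel model, the deposited series values, and each array left out in turn. The fit had no slide term, and slides were tested as a block and singly. Slide 1 held the 28 and 32 °C biological arrays and replicates 1 and 2 of 34 °C. Slide 2 held replicate 3 and the technical arrays, none setting 28 or 32 °C against 24 °C. The separate-channel model did not converge for some probes.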

Results

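Stylophora pistillata, a reef-building coral hosting photosynthetic dinoflagellates, was held in an aquarium warmed from 24 to 34 °C in daily steps of 1 °C. Temperature thus cannot be separated from days of warming. RNA taken at 28, 32 and 34 °C was compared with RNA of 24 °C controls. Each of 14 dual-colour oligonucleotide arrays set one RNA against another. For each temperature, 3 arrays paired heated with control RNA (n = 3 biological arrays), and the remaining 5 were technical arrays, of which 2 set 34 °C against 24 °C RNA and 3 set heated RNAs against each other. The 32 °C biological arrays carried the heated RNA in Cy3 and the 28 and 34 °C biological arrays carried it in Cy5. The labels give the RNA set on each technical array but not which extract of that set, so p-values may be too small. The technical 34 °C against 24 °C arrays correlated across probes at 0.98 and 0.95 with the 34 °C replicate 3 and 2 arrays and were counted as separate arrays. Nor do the labels say which colonies or cultures the biological arrays came from, so p-values measure the spread between these arrays. Of 15208 measuring spots, 72.9% to 94.1% were well above background in each channel except Cy3 of the 32 °C replicate 3 array, where 57% were. The number of arrays limits the precision. Values are log2 fold changes ± SE from one fit over all arrays. Gene names are those of matching database entries, and entries with different names were counted as separate genes.

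The comparison of 28 °C with 24 °C asked which transcripts differed at the first temperature sampled. Carbonic anhydrases, which interconvert carbon dioxide and bicarbonate, showed the largest rises among named genes: CAH6 was 38-fold higher (5.25 ± 0.50, adjusted p = 0.00041) and CAH2_MOUSE (3.94 ± 0.37, adjusted p = 0.00041) followed. GALAXIN (1.90 ± 0.29, adjusted p = 0.00636), named after a coral skeletal matrix protein, and CAH13 (0.94 ± 0.19, adjusted p = 0.0275) also rose. These were the members of the calcification list past the threshold, for which 4 of 54 members rose, 0 fell and 5 passed adjusted over the list alone. The list itself did not pass (adjusted p = 0.773, adjusted p = 0.919 with an estimated correlation), with a mean of 0.093 and a median of -0.082. On its 3 biological arrays alone CAH6 averaged 4.47 ± 0.84 (SD), below the fitted value. CAH13 was well above background in 2 of 11 control channels and GALAXIN in 10 of 11. CAH13 ran from 0.69 to 4.22 over the settings tried, highest with the scanner software's processed signals. CAH13 and GALAXIN lost their calls without the technical 32 °C against 28 °C array (adjusted p = 0.0505 to 0.123). So did CAH13 without the 32 °C replicate 1 array (adjusted p = 0.073), the 34 °C replicate 3 array (0.05003), the technical 34 °C against 24 °C array 2 (0.0512) and the technical 34 °C against 32 °C array (0.0786).

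Chaperones of the endoplasmic reticulum, which fold secreted and membrane proteins, passed as higher at 28 °C (adjusted p = 2.63e-08, adjusted p = 0.109 with an estimated correlation). Of 48 members 8 rose, 1 fell and 16 passed adjusted over the list alone. Calreticulins CALR_CAEEL (1.46 ± 0.26) and CALR_ONCVO (1.38 ± 0.25), the endoplasmin ENPL_CANFA (1.84 ± 0.34) and the stress-induced CREL2_MOUSE (1.31 ± 0.24) rose. Of the heat shock list, 3 of 52 members rose, 0 fell and 6 passed adjusted over the list alone, and the test passed (adjusted p = 0.0208, adjusted p = 0.526 with an estimated correlation). The members were the cytosolic HSP90s H90B3 (1.03 ± 0.16) and HS90B_DANRE (1.32 ± 0.24) and the HSP70 HSP7C_CAEBR (1.36 ± 0.26), while STIP1_MACFA (0.52 ± 0.13, adjusted p = 0.0673), a cochaperone, was not past the threshold. Other genes named in every comparison did not pass: GRP78 as GRP78_CHICK (0.89 ± 0.61), ENPL_CHICK (1.68 ± 0.43), the mitochondrial chaperonin CH60 (0.042 ± 0.17), HSP7C_SAGOE (0.23 ± 0.22), the catalase CATA_RANRU (-0.83 ± 0.27) and the superoxide dismutase SODC (0.44 ± 0.17) had adjusted p of 0.079 to 0.923. No ferritin was measured. A probe named HSP90 was at -0.63. On slide 2 alone H90B3 turned to -0.037. ENPL_CHICK was well above background in 4 of 5 heated channels and CH60 in 2 of 5 heated channels and 1 of 11 control channels. CALR_CAEEL, CALR_ONCVO, CREL2_MOUSE and ENPL_CANFA lost their calls without the technical 32 °C against 28 °C array (adjusted p = 0.0556 to 0.118). So did CREL2_MOUSE, ENPL_CANFA and HSP7C_CAEBR without the technical 34 °C against 32 °C array (adjusted p = 0.0506 to 0.0536), and HSP7C_CAEBR without the 28 °C replicate 3 array (0.0506).

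For the heat shock list at 28 °C the adjusted p was 0.0633 without the 28 °C replicate 1 array, 0.0676 without replicate 2, 0.0584 without the 32 °C replicate 2 array and 0.105 without the technical 34 °C against 28 °C array. The glycolysis list, enzymes of sugar breakdown, passed in the lower direction (adjusted p = 0.0208, adjusted p = 0.109 with an estimated correlation), although 0 of 38 members rose, 0 fell and 4 passed adjusted over the list alone. Its lowest adjusted p were those of G3PA_GUITH (-0.68 ± 0.17, adjusted p = 0.0645), ENOG (-0.82 ± 0.21), HXK2 (-0.59 ± 0.16) and TPIS (-0.48 ± 0.13). That list lost its call without the 32 °C replicate 2 array (adjusted p = 0.0584) and without the technical 32 °C against 28 °C array (0.139). DNA replication genes passed as higher (adjusted p = 2.51e-05, adjusted p = 0.526 with an estimated correlation), yet 0 of 103 members rose, 1 fell and 1 passed adjusted over the list alone, and the gene that fell was ORC6_BOVIN (-0.52 ± 0.11), an origin recognition subunit. Its members CDK2 (0.72 ± 0.18), PCNA_MACFA (1.02 ± 0.34) and RIR2_SCHPO (0.93 ± 0.31) were not past the threshold. Calls also ended for heat shock with median centring, deposited values, slide 2 and fry (adjusted p = 0.171 to 0.722), where its median was -0.096 with median centring, for glycolysis with processed signals, probes bright in every channel, no dye term, extracts apart, the 9 biological arrays, deposited values, slide 2, slide 1 and gene symbols (adjusted p = 0.117 to 0.588) and for DNA replication with extracts apart, slide 2 and fry (adjusted p = 0.202 to 0.713). CDK2 was well above background in 9 of 11 control channels and TPIS in 10 of 11. ORC6_BOVIN lost the call without the 28 °C replicate 3 array (adjusted p = 0.07), the 32 °C replicate 1 array (0.0686), the technical 32 °C against 28 °C array (0.0883), the technical 34 °C against 24 °C array 2 (0.0512) and the technical 34 °C against 32 °C array (0.0787).

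Outside these lists, the chymotrypsin-like protease CTRL (2.49 ± 0.36) and the lectin SAL_SILAS (2.39 ± 0.48) were among the largest rises. The largest falls were HAAF_LIMPO (-3.42 ± 0.35), named after an amebocyte aggregation factor, HEXA (-1.99 ± 0.34), a lysosomal hexosaminidase, the protease PRS33 (-1.92 ± 0.39), the aquaglyceroporin AQP3_RAT (-1.86 ± 0.23) and the alkaline phosphatase PPBI_HUMAN (-1.77 ± 0.26). HAAF_LIMPO averaged -2.27 ± 0.22 (SD, n = 3) on its biological arrays. On slide 2 alone HAAF_LIMPO was at -0.079, and HEXA (0.56) and VWA2 (0.11) turned. In the symbiont list, of labelled probes and plastid genes, 2 of 198 members rose, 4 fell and 14 passed adjusted over the list alone, and the list did not pass (adjusted p = 0.667). Among them were Contig_Sym_2427 (-2.30 ± 0.25), 202_symbiodinum (1.24 ± 0.24) and 2 further symbiont sequences at -2.61 ± 0.30 and 1.13 ± 0.22. In the matrix list 2 of 121 members rose, 1 fell and 11 passed adjusted over the list alone, with the astacin-like proteases NAS7_CAEEL (0.68 ± 0.14) and BP10_PARLI (1.37 ± 0.32) higher and VWA2 (-0.57 ± 0.12) lower (adjusted p = 0.773). Growth factor signalling held FZD1_HUMAN (0.78 ± 0.16) and GDF6A (0.90 ± 0.20) higher and WNT2B_HUMAN (-0.98 ± 0.22) lower. Of 99 members 2 rose, 1 fell and 9 passed adjusted over the list alone (adjusted p = 0.715). Lipid metabolism held HCD2_RAT (1.02 ± 0.20) higher and the lipase PLPL2_MOUSE (-0.66 ± 0.14) lower. Of 107 members 1 rose, 1 fell and 5 passed adjusted over the list alone (adjusted p = 0.66). TSP1_XENLA (1.19 ± 0.28), FGFR1_CHICK (-0.82 ± 0.20), FABL (-0.82 ± 0.20) and MOGT3 (-0.94 ± 0.23) were not past the threshold, and no further list passed. FZD1_HUMAN was well above background in 8 of 11 control channels, WNT2B_HUMAN in 3 of 5 heated channels and 6 of 11 control channels and GDF6A in 9 of 11 control channels. 202_symbiodinum, the symbiont sequence at 1.13, BP10_PARLI, FZD1_HUMAN, GDF6A, HCD2_RAT, NAS7_CAEEL, PLPL2_MOUSE, PRS33, SAL_SILAS, VWA2 and WNT2B_HUMAN lost their calls without the technical 34 °C against 32 °C array (adjusted p = 0.0584 to 0.131). So did 202_symbiodinum, the symbiont sequence at 1.13, BP10_PARLI, FZD1_HUMAN, GDF6A, NAS7_CAEEL, PLPL2_MOUSE, PRS33, SAL_SILAS, VWA2 and WNT2B_HUMAN without the 28 °C replicate 3 array (adjusted p = 0.0517 to 0.086), and the symbiont sequence at 1.13, BP10_PARLI, FZD1_HUMAN, GDF6A, HCD2_RAT, NAS7_CAEEL, PLPL2_MOUSE, PRS33, VWA2 and WNT2B_HUMAN without the 32 °C replicate 1 array (0.0509 to 0.108). So did 202_symbiodinum, BP10_PARLI, FZD1_HUMAN, GDF6A, HCD2_RAT, NAS7_CAEEL, PLPL2_MOUSE and SAL_SILAS without the technical 32 °C against 28 °C array (adjusted p = 0.0626 to 0.23), and BP10_PARLI, GDF6A, PLPL2_MOUSE, VWA2 and WNT2B_HUMAN without the technical 34 °C against 24 °C array 2 (0.0544 to 0.0871). So did BP10_PARLI, PLPL2_MOUSE, VWA2 and WNT2B_HUMAN without the 28 °C replicate 2 array (adjusted p = 0.0521 to 0.0582), and BP10_PARLI, GDF6A, VWA2 and WNT2B_HUMAN without the 34 °C replicate 3 array (0.0536 to 0.0832). So did BP10_PARLI, GDF6A and WNT2B_HUMAN without the technical 34 °C against 24 °C array 1 (adjusted p = 0.0543 to 0.0821), and BP10_PARLI and VWA2 without the technical 34 °C against 28 °C array (0.0538 to 0.0697). So did VWA2 and WNT2B_HUMAN without the 28 °C replicate 1 array (adjusted p = 0.0542 to 0.0677), and BP10_PARLI without the 34 °C replicate 2 array (0.0752).

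At 28 °C 216 of 13662 probes passed, 101 higher and 115 lower in limma at an adjusted p under 0.05, against 2185 at an unadjusted p under 0.05. The count was 218 with slide as a block, 660 on slide 1 alone without a dye term and 18 on slide 2 alone. Lists past the test numbered 4 and were 4, 8 and 8 in the same order. Leaving out single arrays gave 107 without 28 °C replicate 3 and 126 and 601 without 32 °C replicates 1 and 3. The count was 330 and 76 without the technical 32 °C against 28 °C and 34 °C against 32 °C arrays. With the 24 °C extracts kept apart 0 probes passed (603 at an unadjusted p under 0.05), and 3156 did without a dye term. Averaging the technical 34 °C against 24 °C arrays with their closest 34 °C arrays gave 68. Of the 58 genes the naming rule gave at 28 °C 40 were called, and 23 of those lost the call in at least 1 of these omissions and none changed direction.

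**Figure D1:**
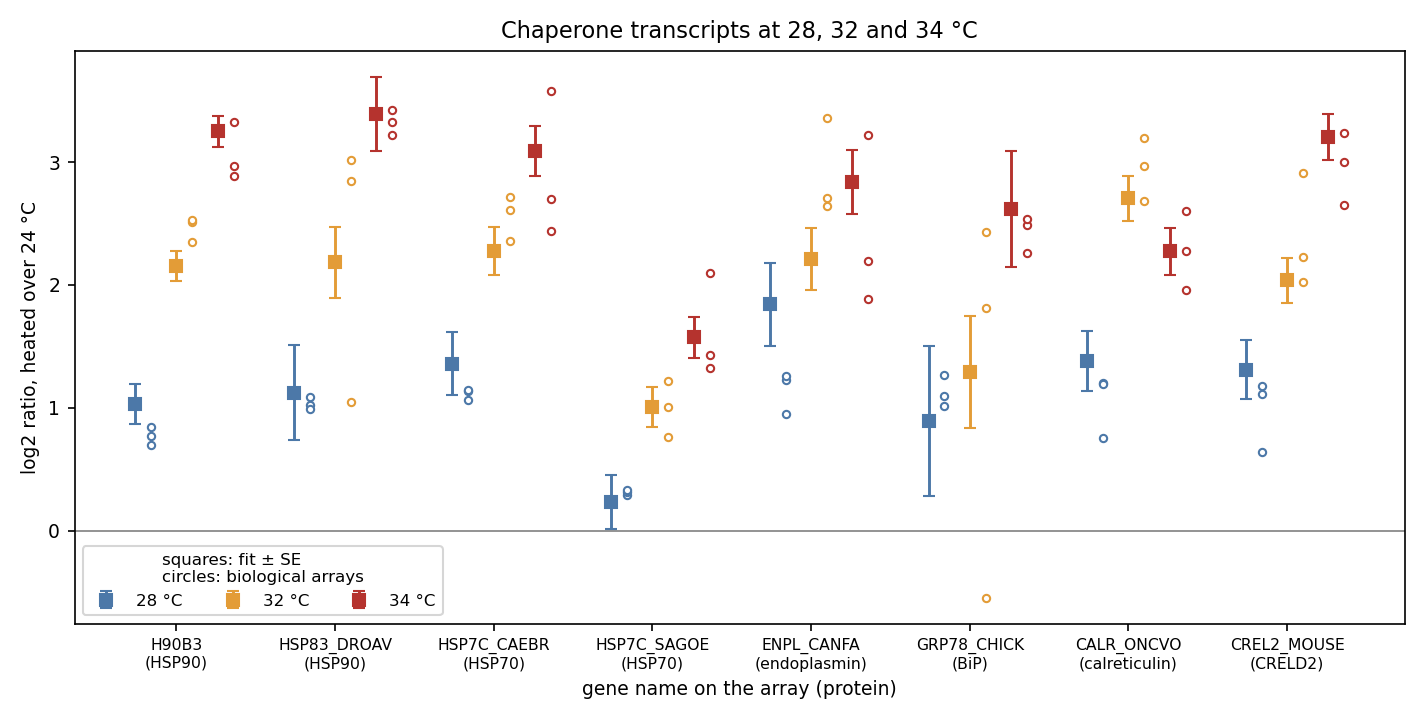
Log2 ratio of heated over 24 °C RNA for chaperone genes at 28, 32 and 34 °C. Small points are the 3 biological arrays and large points with bars are fitted values ± SE, with H90B3 at 1.03, 2.16 and 3.25.

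Lists of protein-folding genes passed as higher at 32 °C. Of the endoplasmic reticulum list 28 of 48 members rose, 0 fell and 32 passed adjusted over the list alone, led by CALR_ONCVO (2.70 ± 0.18, adjusted p = 1.29e-06) and CALR_CAEEL (2.65 ± 0.19), and the test passed (adjusted p = 2.1e-10, adjusted p = 0.0883 with an estimated correlation). Of the heat shock list 26 of 52 members rose, 4 fell and 32 passed adjusted over the list alone (adjusted p = 4.27e-06, adjusted p = 0.0883 with an estimated correlation), with the HSP90s HS90A_RAT (2.51 ± 0.32), H90B3 (2.16 ± 0.12) and HS90B_DANRE (2.13 ± 0.18) and the HSP70 HSP7C_SAGOE (1.01 ± 0.16) higher. The chaperonin and prefoldin list, which folds actin and tubulin, had PFD4 (1.13 ± 0.16) and TCPQ_PONAB (0.61 ± 0.088) higher. Of 16 members 11 rose, 0 fell and 12 passed adjusted over the list alone (adjusted p = 6.02e-06, adjusted p = 0.107 with an estimated correlation). In the degradation and translocation list 8 of 47 members rose, 1 fell and 8 passed adjusted over the list alone (adjusted p = 0.0132, adjusted p = 0.215 with an estimated correlation), with the oligosaccharyltransferase subunit OST48_XENLA (0.68 ± 0.080) and UBXN4 (0.57 ± 0.081). ENPL_CHICK (2.33 ± 0.32) rose. GRP78_CHICK (1.29 ± 0.45, adjusted p = 0.0461) and CH60 (0.36 ± 0.12, adjusted p = 0.045) rose on 2 of 3 biological arrays each. Those calls ended in 12 and 11 of the 14 fits that left out an array (adjusted p up to 0.362 and 0.211). A probe named HSP90 fell (-0.80). The call ended for degradation and translocation with processed signals, probes bright in every channel, extracts apart, deposited values and gene symbols (adjusted p = 0.0505 to 0.255). CH60 ran from 0.051 to 1.78 over the settings tried. CH60 was well above background in 2 of 5 heated channels and 1 of 11 control channels and ENPL_CHICK in 4 of 5 heated channels.

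Lists of protein turnover, redox defence and respiration also passed as higher at 32 °C. In the proteasome and ubiquitin list 55 of 143 members rose, 6 fell and 65 passed adjusted over the list alone (adjusted p = 6.02e-06, adjusted p = 0.107 with an estimated correlation), with the core subunits PSA7A (1.24 ± 0.14) and PSA7 (1.13 ± 0.095). Antioxidant enzymes included SODC (1.01 ± 0.13), which removes superoxide, and the peroxiredoxin PRDX6_CHICK (1.21 ± 0.16). Of 69 members 29 rose, 5 fell and 38 passed adjusted over the list alone (adjusted p = 3.12e-05, adjusted p = 0.107 with an estimated correlation). Of catalases only CATA_RANRU (1.03 ± 0.20, adjusted p = 0.00196) rose, on 2 of 3 biological arrays. Respiratory chain and TCA cycle genes passed as higher (adjusted p = 6.02e-06, adjusted p = 0.13 with an estimated correlation). Of 111 members 52 rose, 11 fell and 66 passed adjusted over the list alone. The smallest adjusted p belonged to cytochrome b probes that fell, CYB_PHYME (-1.73 ± 0.19) and CYB_DROMA (-1.58 ± 0.18), both named after non-cnidarian entries. Ribosome biogenesis had the nucleolar NOP2 (0.83 ± 0.11) higher and the elongation factor EF2_RAT (-1.42 ± 0.20) lower. Of 147 members 47 rose, 8 fell and 56 passed adjusted over the list alone (adjusted p = 9.18e-05, adjusted p = 0.103 with an estimated correlation). DNA replication had ORC1_BOVIN (0.77 ± 0.096) and the sliding clamp PCNA_XENLA (1.08 ± 0.15) higher. Of 103 members 41 rose, 5 fell and 48 passed adjusted over the list alone (adjusted p = 6.3e-06, adjusted p = 0.13 with an estimated correlation).

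Lists passing as lower at 32 °C covered signalling, matrix and symbiont transcripts. Growth factor signalling had the ligand BMP7 (-1.03 ± 0.11) and the inhibitor SMAD6_HUMAN (-0.98 ± 0.14) lower. Of 99 members 5 rose, 28 fell and 34 passed adjusted over the list alone (adjusted p = 9.18e-05, adjusted p = 0.107 with an estimated correlation). In the matrix list 7 of 121 members rose, 32 fell and 39 passed adjusted over the list alone (adjusted p = 0.00485, adjusted p = 0.107 with an estimated correlation), with FBLN2 (-1.85 ± 0.16) and the cadherin CAD96_DROME (-0.91 ± 0.12). Ribosomal proteins passed as lower but turned to a median of 0.19 with median centring (adjusted p = 0.23). Of 119 members 4 rose, 23 fell and 26 passed adjusted over the list alone (adjusted p = 0.00833, adjusted p = 0.13 with an estimated correlation), although RL20 (0.79 ± 0.11) rose while RL11_RAT (-0.47 ± 0.076) fell. In the circadian list 1 of 17 members rose, 7 fell and 9 passed adjusted over the list alone (adjusted p = 0.0179, adjusted p = 0.107 with an estimated correlation), with the melatonin-related receptor MTR1L (-0.87 ± 0.10) and HLF (-1.28 ± 0.21). Innate immunity held the lectin LECB6 (-1.71 ± 0.29) lower and GILT_HUMAN (0.64 ± 0.087), a thiol reductase, higher. Of 75 members 7 rose, 14 fell and 20 passed adjusted over the list alone (adjusted p = 0.0229, adjusted p = 0.0883 with an estimated correlation), and its adjusted p was 0.0527 without the technical 32 °C against 28 °C array. In the symbiont list 38 of 198 members rose, 62 fell and 118 passed adjusted over the list alone (adjusted p = 0.0166, adjusted p = 0.215 with an estimated correlation), with 150_symbiodinum (1.77 ± 0.097) and 202_symbiodinum (1.82 ± 0.18) higher. Calls ended for matrix with gene symbols (adjusted p = 0.282), ribosomal proteins with processed signals, median centring, no dye term, extracts apart, the 9 biological arrays, deposited values and slide 1 (adjusted p = 0.0583 to 0.49), circadian genes with no dye term, extracts apart, the 9 biological arrays, slide 1 and gene symbols (adjusted p = 0.0664 to 0.421), innate immunity with processed signals, median centring, probes bright in every channel, slide 2 and gene symbols (adjusted p = 0.05001 to 0.151) and symbiont genes with no dye term, the 9 biological arrays and slide 1 (adjusted p = 0.0733 to 0.0958).

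The largest falls at 32 °C were the plastid gene PSBB (-3.66 ± 0.83), NRF6_CAEEL (-3.07 ± 0.19), the sulfate transporter S26A2 (-2.92 ± 0.36), the transcription factor EGR1 (-2.76 ± 0.40) and CYB6 (-2.71 ± 0.45), a plastid cytochrome. Beside chaperones, the largest rises were the peroxidases MLT7_CAEEL (2.50 ± 0.25) and PXDN_HUMAN (2.34 ± 0.42). In the calcification list 8 of 54 members rose, 11 fell and 20 passed adjusted over the list alone, with GALAXIN (1.45 ± 0.22) higher, and the test did not pass (adjusted p = 0.407). On the technical array of 32 °C over 28 °C RNA, PSBB was at -0.096 and CYB6 at -0.19. PSBB lost the call without the technical 34 °C against 28 °C array (adjusted p = 0.0611). CYB6 was well above background in 4 of 5 heated channels, GALAXIN in 10 of 11 control channels and MTR1L in 10 of 11. In limma 4004 of 13662 probes passed, 2168 higher and 1836 lower. The count was 4012 with slide as a block, 3885 on slide 1 and, with no direct array, 5066 on slide 2. Lists past the test numbered 15 and were 15, 14 and 14 in the same order. Leaving out single arrays gave 2042 without the technical 34 °C against 28 °C array and 2324 without the technical 34 °C against 32 °C array, and keeping the 24 °C extracts apart gave 146.

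**Figure D2:**
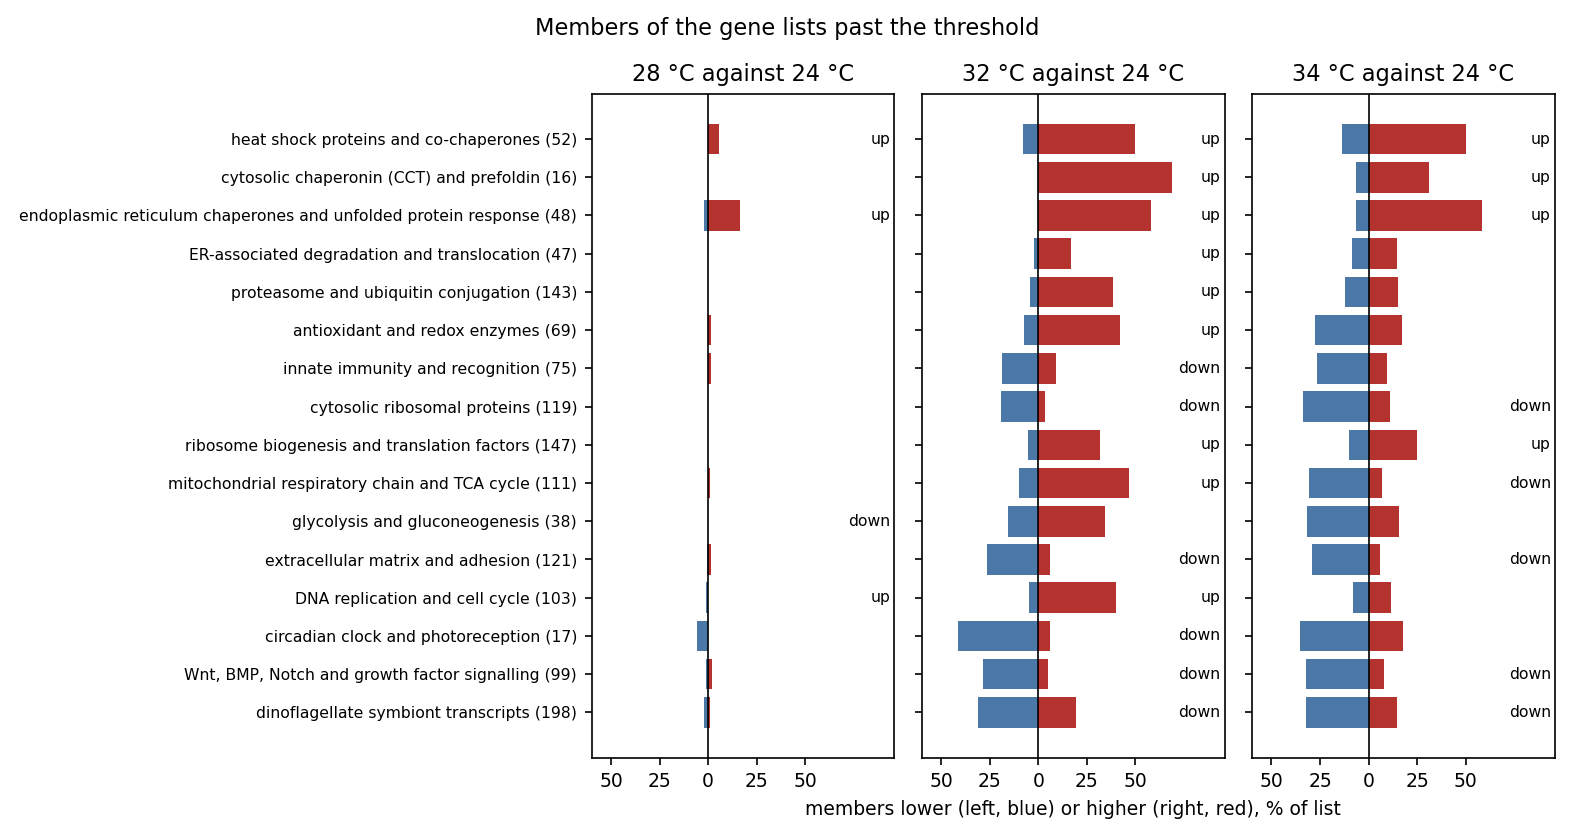
Share of each gene list's members past the threshold, lower to the left and higher to the right, in % of the list, at 28, 32 and 34 °C against 24 °C. The words up and down mark lists past the preset-correlation test, 4, 15 and 9 of them, none of which passed with an estimated correlation.

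At 34 °C chaperones showed the largest rises among named genes. The cytosolic HSP90s HSP83_DROAV (3.39 ± 0.30) and H90B3 (3.25 ± 0.13), the HSP70 HSP7C_CAEBR (3.09 ± 0.20), CREL2_MOUSE (3.20 ± 0.19) and ENPL_CANFA (2.84 ± 0.26) were higher on 3 of 3 biological arrays. Of the heat shock list 26 of 52 members rose, 7 fell and 36 passed adjusted over the list alone (adjusted p = 1.29e-07, adjusted p = 0.0988 with an estimated correlation), and of the endoplasmic reticulum list 28 of 48 members rose, 3 fell and 32 passed adjusted over the list alone (adjusted p = 1.43e-08, adjusted p = 0.0988 with an estimated correlation), with DJC10 (1.38 ± 0.10), a disulfide reductase. GRP78_CHICK (2.62 ± 0.47, adjusted p = 0.000835), ENPL_CHICK (2.73 ± 0.29), HSP7C_SAGOE (1.57 ± 0.17) and CH60 (0.80 ± 0.13) rose. The chaperonin list had TCPQ_CHICK (1.25 ± 0.12) higher and PFD3_PONAB (-0.78 ± 0.14) lower. Of 16 members 5 rose, 1 fell and 7 passed adjusted over the list alone (adjusted p = 0.0173, adjusted p = 0.447 with an estimated correlation). Its adjusted p was 0.0551 without the 32 °C replicate 3 array and 0.118 without the technical 32 °C against 28 °C array. Probes named HSP74 and HSP90 fell (-0.55 and -0.63). The catalase CATA_RANRU (-0.73 ± 0.21, adjusted p = 0.0154) fell and SODC (-0.050 ± 0.13, adjusted p = 0.815) did not pass. The call also ended for chaperonin with median centring, probes bright in every channel, extracts apart and slide 2 (adjusted p = 0.0749 to 0.213). CH60 ran from 0.65 to 3.11 over the settings tried, highest with processed signals. CH60 was well above background in 1 of 11 control channels. CATA_RANRU lost the call without the technical 34 °C against 32 °C array (adjusted p = 0.0894). So did PFD3_PONAB without the technical 34 °C against 28 °C array (adjusted p = 0.0554).

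Mitochondrial, ribosomal, matrix and signalling lists passed as lower at 34 °C. Of respiratory chain and TCA cycle genes 8 of 111 members rose, 34 fell and 44 passed adjusted over the list alone (adjusted p = 0.0167, adjusted p = 0.524 with an estimated correlation), with cytochrome b probes CYB_DROMA (-3.47 ± 0.18) and CYB_PHYME (-3.45 ± 0.20). Ribosomal proteins passed as lower (adjusted p = 0.0158, adjusted p = 0.243 with an estimated correlation), with RS6_RAT (-0.77 ± 0.097) lower and RL5_RAT (1.01 ± 0.093) higher. Of 119 members 13 rose, 40 fell and 54 passed adjusted over the list alone. Ribosome biogenesis passed as higher (adjusted p = 0.00322, adjusted p = 0.177 with an estimated correlation), with RRP7A (1.43 ± 0.14) and NOP2 (1.13 ± 0.12). Of 147 members 37 rose, 15 fell and 52 passed adjusted over the list alone. In the matrix list 7 of 121 members rose, 35 fell and 47 passed adjusted over the list alone (adjusted p = 0.0167, adjusted p = 0.243 with an estimated correlation), with the collagen CO6A5 (-2.41 ± 0.14) and FBLN2 (-1.95 ± 0.17). Growth factor signalling had SMAD6_HUMAN (-1.82 ± 0.15) lower and the ligand WNT8B_DANRE (2.13 ± 0.19) higher. Of 99 members 8 rose, 32 fell and 43 passed adjusted over the list alone (adjusted p = 0.00343, adjusted p = 0.257 with an estimated correlation). In the symbiont list 29 of 198 members rose, 64 fell and 96 passed adjusted over the list alone (adjusted p = 0.0414, adjusted p = 0.428 with an estimated correlation), with 150_symbiodinum (2.00 ± 0.10) and 202_symbiodinum (2.49 ± 0.19) higher. Without the technical 32 °C against 28 °C array the adjusted p was 0.118 for ribosomal proteins, 0.118 for matrix, 0.0527 for signalling and 0.334 for symbiont genes. Without the 32 °C replicate 3 array it was 0.0784 for mitochondrial and 0.0574 for symbiont genes, and the latter had 0.0591 without replicate 2. Calls also ended for respiration with processed signals, no dye term, extracts apart, the 9 biological arrays, slide 2, slide 1 and gene symbols (adjusted p = 0.0672 to 0.58), ribosomal proteins with processed signals (adjusted p = 0.248), ribosome biogenesis with median centring, slide 2 and gene symbols (adjusted p = 0.0516 to 0.239), matrix with median centring, extracts apart and gene symbols (adjusted p = 0.0528 to 0.353), signalling with probes bright in every channel (adjusted p = 0.226) and symbiont genes with processed signals, no filter, probes bright in every channel, extracts apart and a slide block (adjusted p = 0.0528 to 0.218).

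The largest falls at 34 °C were CUZD1_RAT (-4.73 ± 0.55), the plastid gene PSBB (-4.31 ± 0.86), the sulfate transporter S26A2 (-4.24 ± 0.37), NRF6_CAEEL (-4.08 ± 0.19) and PAO_MAIZE (-3.99 ± 0.58), a polyamine oxidase. On the technical array of 34 °C over 28 °C RNA, PSBB was at -0.85. In the calcification list 5 of 54 members rose, 11 fell and 16 passed adjusted over the list alone, with CAH14 (-2.81 ± 0.32) lower, and the test did not pass (adjusted p = 0.191). S26A2 was well above background in 6 of 7 heated channels, NRF6_CAEEL in 3 of 7 and FBLN2 in 6 of 7. In limma 4426 of 13662 probes passed, 1970 higher and 2456 lower at an adjusted p under 0.05. The count was 4206 with slide as a block and 3189 and 2184 on slides 1 and 2 alone. Lists past the test numbered 9 and were 8, 10 and 8 in the same order. Leaving out single arrays gave 2608 without the technical 34 °C against 28 °C array, and without the technical 32 °C against 28 °C array 4 lists passed, against 6 without the 32 °C replicate 3 array. Keeping the 24 °C extracts apart gave 463 probes.

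**Figure D3:**
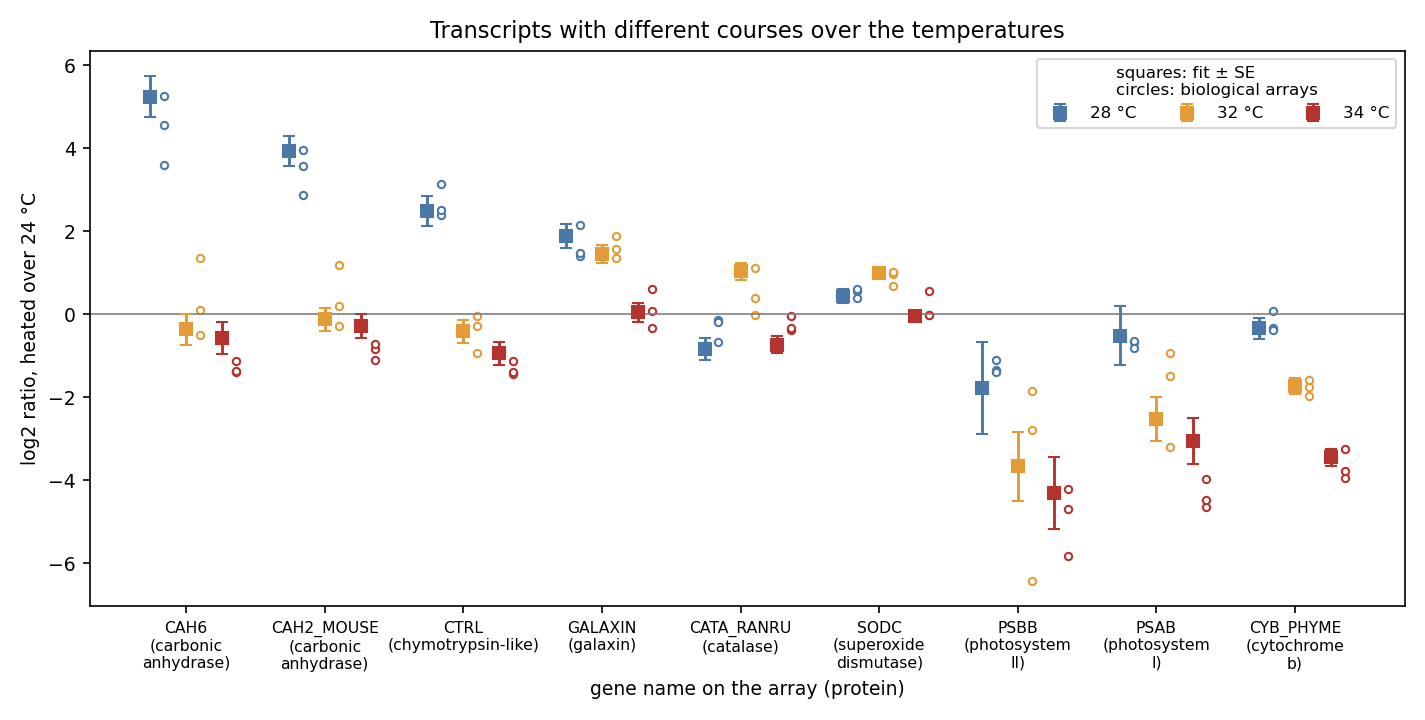
Log2 ratio of heated over 24 °C RNA for genes with different courses over 28, 32 and 34 °C. Small points are biological arrays and large points with bars are fitted values ± SE, with CAH6 at 5.25 at 28 °C and CYB_PHYME at -1.73 and -3.45 at 32 and 34 °C.

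Between 28 and 32 °C, the carbonic anhydrases CAH6 (-5.60 ± 0.76, adjusted p = 0.0122) and CAH2_MOUSE (-4.06 ± 0.56) and the protease CTRL (-2.90 ± 0.56, adjusted p = 0.0388) were lower at 32 °C. CAH2_MOUSE and CAH6 lost their calls without the technical 34 °C against 32 °C array (adjusted p = 0.0846). CTRL lost its call in 10 of the omissions (adjusted p up to 0.217). The chaperones and antioxidants GRP78_CHICK (0.40 ± 0.93), ENPL_CHICK (0.65 ± 0.71), CH60 (0.31 ± 0.25), HSP7C_SAGOE (0.77 ± 0.33), H90B3 (1.12 ± 0.25), CATA_RANRU (1.86 ± 0.41) and SODC (0.57 ± 0.26) did not pass, with adjusted p of 0.0645 to 0.879. Lists passing as higher are given with the adjusted p for the preset and then for the estimated correlation. They were heat shock (0.00436, 0.206), chaperonin (0.00436, 0.246), endoplasmic reticulum chaperones (0.0058, 0.246) and proteasome (3.81e-05, 0.206). Antioxidants (0.000117, 0.206), ribosome biogenesis (0.00695, 0.206), respiration (0.000978, 0.246) and glycolysis (0.0257, 0.206) were also higher. Matrix (adjusted p = 0.00436, adjusted p = 0.206 with an estimated correlation) and growth factor signalling (adjusted p = 0.00436, adjusted p = 0.227 with an estimated correlation) passed as lower. Ribosomal proteins passed as lower (adjusted p = 0.00436, adjusted p = 0.206 with an estimated correlation) but as higher with median centring (median 0.48, adjusted p = 0.00978), and the direction of their test also turned on slide 2 alone (median -0.017, adjusted p = 0.932). In respiration 2 of 111 members rose, 0 fell and 2 passed adjusted over the list alone, and in glycolysis 3 of 38 members rose, 0 fell and 4 passed adjusted over the list alone. In limma 80 of 13662 probes passed, 48 higher and 32 lower, against 2039 at an unadjusted p under 0.05. The count was 61 with slide as a block and 963 and 95 on slides 1 and 2 alone. Leaving out single arrays gave 29 and 11 without 28 °C replicates 1 and 3. It was 25, 133 and 560 without 32 °C replicates 1, 2 and 3 and 41, 10 and 7 without those of 34 °C. It was 8 and 14 without the technical 34 °C against 24 °C arrays 1 and 2. Without the technical 32 °C against 28 °C, 34 °C against 28 °C and 34 °C against 32 °C arrays it was 760, 11 and 0. Without 32 °C replicate 2 or 3 the adjusted p was 0.0593 or 0.0575 for glycolysis. Without the technical 32 °C against 28 °C array it was 0.478 for heat shock, 0.142 for endoplasmic reticulum chaperones, 0.119 for ribosome biogenesis and 0.237 for glycolysis. Without the technical 34 °C against 28 °C array it was 0.0629 for chaperonin and 0.132 for ribosome biogenesis. Averaging the technical 34 °C against 24 °C arrays with their closest arrays gave 0. That omission with 0 and this fit had 1052 and 1533 at an unadjusted p under 0.05 in limma.

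Between 28 and 34 °C, CAH6 (-5.82 ± 0.32), CAH2_MOUSE (-4.22 ± 0.24), CTRL (-3.43 ± 0.23) and GALAXIN (-1.85 ± 0.19) were lower at 34 °C, and H90B3 (2.22 ± 0.11), HSP7C_CAEBR (1.73 ± 0.17), HSP7C_SAGOE (1.34 ± 0.14), GRP78_CHICK (1.73 ± 0.39, adjusted p = 0.00307), ENPL_CHICK (1.06 ± 0.25) and CH60 (0.76 ± 0.11) were higher. CYB_PHYME (-3.11 ± 0.16), RS6_RAT (-0.77 ± 0.080) and SODC (-0.49 ± 0.11) fell, and CATA_RANRU (0.097 ± 0.17, adjusted p = 0.679) did not pass. Heat shock (30 of 52 members rose, 4 fell and 36 passed adjusted over the list alone, adjusted p = 2.9e-05, adjusted p = 0.238 with an estimated correlation), endoplasmic reticulum chaperones (24 of 48 members rose, 5 fell and 30 passed adjusted over the list alone, adjusted p = 0.00254, adjusted p = 0.295 with an estimated correlation) and ribosome biogenesis (51 of 147 members rose, 16 fell and 68 passed adjusted over the list alone, adjusted p = 0.0104, adjusted p = 0.25 with an estimated correlation) passed as higher. Passing as lower were ribosomal proteins (15 of 119 members rose, 51 fell and 71 passed adjusted over the list alone, adjusted p = 0.00281, adjusted p = 0.238 with an estimated correlation), respiration (9 of 111 members rose, 44 fell and 54 passed adjusted over the list alone, adjusted p = 0.00232, adjusted p = 0.403 with an estimated correlation), matrix (11 of 121 members rose, 41 fell and 54 passed adjusted over the list alone, adjusted p = 0.0104, adjusted p = 0.25 with an estimated correlation) and signalling (13 of 99 members rose, 40 fell and 53 passed adjusted over the list alone, adjusted p = 0.0132, adjusted p = 0.39 with an estimated correlation). Cnidocyte markers, genes of stinging cells, passed as lower (adjusted p = 0.0201, adjusted p = 0.25 with an estimated correlation), with the toxins TX60A (-1.86 ± 0.38) and TX60B (-0.55 ± 0.078). Of 5 members 0 rose, 4 fell and 4 passed adjusted over the list alone. In limma 5734 of 13662 probes passed, 2815 higher and 2919 lower. The count was 5702 with slide as a block and 1477 and 4807 on slides 1 and 2 alone. Leaving out any 1 array ended none of these list calls.

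Between 32 and 34 °C, the respiratory chain list passed as lower at 34 °C (0 of 111 members rose, 37 fell and 50 passed adjusted over the list alone, adjusted p = 7.69e-10, adjusted p = 0.486 with an estimated correlation), with the complex III subunit QCR6 (-1.33 ± 0.23) and CYB_PHYME (-1.72 ± 0.33), while QCR9 (-0.95 ± 0.31, adjusted p = 0.0668) did not pass. Antioxidants (1 of 69 members rose, 18 fell and 23 passed adjusted over the list alone, adjusted p = 0.000654, adjusted p = 0.615 with an estimated correlation) included CATA_RANRU (-1.76 ± 0.35), SODC (-1.06 ± 0.23) and the glutathione transferase GSTM3 (-1.49 ± 0.15). Proteasome genes (4 of 143 members rose, 27 fell and 38 passed adjusted over the list alone, adjusted p = 0.0206, adjusted p = 0.825 with an estimated correlation) included PSA7 (-1.57 ± 0.17), and DNA replication also passed as lower (1 of 103 members rose, 13 fell and 16 passed adjusted over the list alone, adjusted p = 0.0245, adjusted p = 0.863 with an estimated correlation). The histone H2AX_DANRE (-2.35 ± 0.32) fell and H90B3 (1.09 ± 0.22) rose. HS90A_RAT (-1.11 ± 0.57, adjusted p = 0.248) and GRP78_CHICK (1.32 ± 0.80), ENPL_CHICK (0.40 ± 0.56), CH60 (0.44 ± 0.22) and HSP7C_SAGOE (0.56 ± 0.29) did not pass. CATA_RANRU, H2AX_DANRE, H90B3, QCR6 and SODC lost their calls without the technical 34 °C against 28 °C array (adjusted p = 0.0533 to 0.194). So did CATA_RANRU, CYB_PHYME, H90B3, QCR6 and SODC without the technical 34 °C against 32 °C array (adjusted p = 0.0609 to 0.116), and CYB_PHYME without the technical 32 °C against 28 °C array (0.0642). In limma 1344 of 13662 probes passed, 370 higher and 974 lower. The split was 716 higher and 653 lower on the 9 biological arrays and 2243 and 2189 without a dye term. The count was 1423 with slide as a block and 291 and 4205 on slides 1 and 2 alone. Leaving out single arrays gave 3033 without the 32 °C replicate 3 array, 104 without the technical 34 °C against 28 °C array and 144 without the technical 34 °C against 32 °C array. Without the 32 °C replicate 3 array the adjusted p was 0.118 for proteasome. Without the technical 32 °C against 28 °C array it was 0.131 for DNA replication. Without the technical 34 °C against 28 °C array it was 0.0792 for proteasome and 0.518 for DNA replication.

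Across genes, which are not independent replicates, log2 fold changes correlated at r = 0.31 between 28 and 32 °C, 0.38 between 28 and 34 °C and 0.40 between 32 and 34 °C. Unchanged groups simulated with the same shared controls and dye term gave -0.52, 0.76 and -0.50. Observed covariances were 0.054, 0.0762 and 0.106, and exceeded the simulated ones of -0.0228, 0.0347 and -0.0171 by 0.0768, 0.0415 and 0.123. With the 24 °C extracts kept apart these differences were 0.075, -0.037 and 0.161. The 9 biological arrays, which share no array between temperatures, gave r = 0.34, 0.23 and 0.61. With the overlap of independent lists in parentheses, probes higher at both 32 and 34 °C numbered 691 (313), those lower at both 764 (330) and those in opposite directions 387 (654). For 28 and 32 °C the numbers were 45 (16), 60 (15.5) and 11 (31.8), and for 28 and 34 °C 47 (14.6), 75 (20.7) and 18 (34.7). Part of the overlaps in 1 direction for 28 and 34 °C, and of the opposite ones for the other pairs, can come from the shared controls and dye term.

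The 24 °C extracts were labelled as 3 control sets. Among 13652 probes testable for differences between them, 0 passed in limma and 259 had an unadjusted p under 0.05. Without the technical 34 °C against 32 °C array 1 probe passed (adjusted p = 0.00924). This test had few arrays per control set, so it does not show that the sets were alike.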

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

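Only after the result was seen were these tests chosen: the dye and symbiont tests of the organelle transcripts, both tests of the 28 °C rises and the correlations of other assignments with the real fold changes. The 28 °C set was first tested on 9 of its probes, those lower at 34 °C than at 28 °C. It was widened to all 10 after that value was seen, because the narrower choice partly fixed the outcome.

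Among the genes the naming rule gives, 13 passed in opposite directions at 32 and 34 °C against 24 °C, with log2 differences, in parentheses, past the test of 34 °C against 32 °C. From 32 to 34 °C the histone H2AX_DANRE went from 1.24 to -1.11 (-2.35). MEIG1_NEMVE went from 0.79 to -1.29 (-2.08), and MATN2_HUMAN went from 1.12 to -0.89 (-2.01). The fructose bisphosphatase F16P2_BOVIN went from 1.28 to -0.60 (-1.88). The catalase CATA_RANRU went from 1.03 to -0.73 (-1.76), and the tubulin TBB1_CAEEL went from 1.11 to -0.55 (-1.66). The proteasome subunit PSA7 went from 1.13 to -0.44 (-1.57). The cell cycle kinase CDC2_ORYLU went from 0.73 to -0.82 (-1.56), and the repair factor RD23B_HUMAN went from 0.90 to -0.65 (-1.54). The glutathione transferase GSTM3 went from 0.50 to -0.997 (-1.49). The ribosomal protein RL20 went from 0.79 to -0.61 (-1.39), and the prefoldin PFD3_PONAB went from 0.46 to -0.78 (-1.24). The toxin TX60B went from 0.50 to -0.45 (-0.95). The respiratory chain list passed as higher at 32 °C and lower at 34 °C, and differed between them with an adjusted p of 7.69e-10 (adjusted p = 0.486 with an estimated correlation). Its 34 °C call ended on the 9 biological arrays (median -0.077, adjusted p = 0.524), on each slide alone and without a dye term (0.13), among others. On the 9 biological arrays the 34 °C values of F16P2_BOVIN (0.32), PSA7 (0.13), RL20 (0.023) and TBB1_CAEEL (0.28) were above 0, and some turned on slide 1, slide 2 or without a dye term, so their opposite directions depend on the model. Single biological arrays gave CATA_RANRU -0.019 to 1.12 at 32 °C and -0.37 to -0.032 at 34 °C. Its difference between them ran from -2.36 to -0.70 over the settings tried. Of the calls of 34 °C against 32 °C, CATA_RANRU, CDC2_ORYLU, F16P2_BOVIN, H2AX_DANRE, MEIG1_NEMVE, PFD3_PONAB, RL20, TBB1_CAEEL and TX60B lost their calls without the technical 34 °C against 28 °C array (adjusted p = 0.0533 to 0.251). So did CATA_RANRU, CDC2_ORYLU, F16P2_BOVIN, MEIG1_NEMVE, PFD3_PONAB and TBB1_CAEEL without the technical 34 °C against 32 °C array (adjusted p = 0.0639 to 0.116). Of those of 32 °C against 24 °C, CDC2_ORYLU, MEIG1_NEMVE and PFD3_PONAB lost their calls without the technical 34 °C against 28 °C array (adjusted p = 0.0601 to 0.202). So did MEIG1_NEMVE and PFD3_PONAB without the technical 34 °C against 32 °C array (adjusted p = 0.115 to 0.136). Of those of 34 °C against 24 °C, CDC2_ORYLU, F16P2_BOVIN, MEIG1_NEMVE, PFD3_PONAB, PSA7, RL20, TBB1_CAEEL and TX60B lost their calls without the technical 34 °C against 28 °C array (adjusted p = 0.0519 to 0.258). So did CATA_RANRU, F16P2_BOVIN and TBB1_CAEEL without the technical 34 °C against 32 °C array (adjusted p = 0.0894 to 0.159), and F16P2_BOVIN without the 32 °C replicate 1 array (0.0579).

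Altogether 387 probes passed in opposite directions at 32 and 34 °C, 324 of them higher at 32 °C, and simulated unchanged groups correlated at -0.50 between these temperatures. Dye bias and differing 24 °C extracts both cancel in the difference of the technical arrays of 34 °C and 32 °C over 28 °C RNA, and 100% of 218 probes called in the other 12 arrays went in the called order there. Without the dim 32 °C replicate 3 array 100% of 387 kept opposite signs, but the calls used it. In the 9 biological arrays without a dye term 151 probes were opposite, of which 94% went in the called order in those technical arrays and 42 were among the 387, so which probes are called depends on the model. A difference between 32 and 34 °C may be biological for part of the 387, a hypothesis from the same data, and whether it crosses the 24 °C level stays open. The dim array and extracts shared by technical arrays stay open.

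Plastid genes and cytochrome probes named after non-cnidarian entries, 9 in all, had a median of -1.73 at 32 °C and -3.05 at 34 °C, where 9 passed as lower, but technical arrays over 28 °C RNA gave the plastid genes -0.096 at 32 °C and -0.67 at 34 °C and the cytochrome probes -0.66 and -2.10 (medians). Against dye bias, the 32 °C biological arrays, with the opposite dye, gave a median of -1.77 (range -3.69 to -1.20). The 100 probes nearest in brightness to each had a median of -0.082 at 34 °C. Loess within each array sets ratios near 0 at every brightness, so this cannot test a scaling effect on bright probes. Against a lower share of symbiont RNA as the whole cause, symbiont-labelled probes had a median of -0.25, with 59 of 189 lower and 29 higher. A lower level of transcript is a candidate explanation for the cytochrome probes, as a hypothesis, the fall of the plastid genes from 28 °C is left open, and which organism each probe reads stays open, since 7 mitochondrial probes named after cnidarian entries had a median of -0.24 with 1 lower.

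The 10 largest rises at 28 °C had a median of 1.67 on the biological arrays. A low level in control set C1, or the dye, would also raise 34 °C RNA over C1, which had the same dyes, and that median was -0.21 (range -1.99 to 1.92), highest for ENPL_CANFA. On technical arrays without control RNA, which also entered the fit that picked these probes, 28 °C over 32 °C gave a median of 1.99 and 28 °C over 34 °C one of 2.00. Past the threshold, 9 were lower at 34 °C than at 28 °C and 5 were lower at 32 °C, while GALAXIN (1.45 ± 0.22) and ENPL_CANFA were also higher at 32 °C than at 24 °C, as were MDGA1_MOUSE (1.03) and ENPL_CANFA at 34 °C. A rise at 28 °C with a lower level at 34 °C may be biological for all but ENPL_CANFA, as a hypothesis. Whether the rise was limited to 28 °C, days of warming and differences between the sampled colonies or cultures stay open.

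Chance was checked with 100 assignments of the 14 arrays to the hybridisations of the design, the real one included. For probes, 3, 2 and 1 gave as many at 28, 32 and 34 °C (real 216, 4004, 4426, highest other 2484, 4300, 1503). At 32 °C against 28 °C 4 did (real 80, highest other 3089). At 34 °C against 28 °C 1 did (real 5734, highest other 4799). At 34 °C against 32 °C 3 did (real 1344, highest other 1751). Each share was under 0.05, uncorrected over the counts. Chance stays open for 32 °C against 28 °C, which some settings left at 0. At 28 °C against 24 °C and 32 °C against 28 °C an assignment called many times the real count, and the cause was not tested. The fold changes of these assignments correlated across probes at -0.81 with the real ones at 34 °C and at 0.87 with those at 32 °C, respectively. For lists, 66, 2 and 38 gave as many at 28, 32 and 34 °C, so chance was not excluded at 28 and 34 °C. Real counts were 4, 15 and 9, the highest others 16, 15 and 16 and the median others 7, 6 and 6. The count at 32 °C does not cover each list, since for 11 of its 15 lists at least 5 assignments gave as small a preset p, up to 32 for ribosomal proteins, and fewer did for chaperonin (1), antioxidants (1), proteasome (3) and circadian genes (4). At 28 °C as many did for heat shock (38) and DNA replication (13) but fewer for endoplasmic reticulum chaperones (4) and glycolysis (1), and at 34 °C fewer did for heat shock (1) and endoplasmic reticulum chaperones (3) alone.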

How the results depend on the processing

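The settings by slide block, by single slide, by leaving out or averaging technical 34 °C arrays with their closest array, by gene symbols and all settings for lists between heated temperatures were chosen after seeing the data. Aquantile scaling changed nothing because it leaves log ratios as they are. No background subtraction, no filter, the replicate block and the slide block with a dye coefficient per slide kept every probe count within 1.5 times of the reported one. Counts of probes moved further in the following settings. The scanner software's processed signals gave 51 at 28 °C and 1 at 32 °C against 28 °C. Median centring gave 13 at 32 °C against 28 °C. Probes well above background in every channel gave 3553 at 34 °C against 28 °C. No dye term gave 3156 at 28 °C, 7479 at 34 °C, 2919 at 32 °C against 28 °C and 4432 at 34 °C against 32 °C. The 24 °C extracts kept apart gave 0 at 28 °C, 146 at 32 °C, 463 at 34 °C, 0 at 32 °C against 28 °C, 3219 at 34 °C against 28 °C and 895 at 34 °C against 32 °C. The 9 biological arrays gave 880 at 28 °C, 1329 at 32 °C against 28 °C and 2508 at 34 °C against 28 °C. The technical 34 °C arrays averaged gave 7 at 32 °C against 28 °C. Slide as a random block gave 45 at 32 °C against 28 °C. A separate-channel model gave 1178 at 28 °C, 6599 at 32 °C, 863 at 32 °C against 28 °C and 4863 at 34 °C against 32 °C. The authors' deposited values gave 64 at 28 °C and 52 at 32 °C against 28 °C. Slide 2 only gave 18 at 28 °C, 2184 at 34 °C and 4205 at 34 °C against 32 °C. Slide 1 only gave 660 at 28 °C, 963 at 32 °C against 28 °C, 1477 at 34 °C against 28 °C and 291 at 34 °C against 32 °C. Averaging each technical 34 °C array with its closest array gave 68 at 28 °C and 0 at 32 °C against 28 °C. Leaving out the technical 34 °C against 24 °C arrays gave 51 at 28 °C, 0 at 32 °C against 28 °C and 787 at 34 °C against 32 °C. At an unadjusted p under 0.05 the settings with 0 probes for 32 °C against 28 °C had 1268, 1533 and 1478 in limma. The cause was not tested, except that fewer arrays or probes entered some settings. Leaving out each array in turn gave 76 to 601 at 28 °C, 2042 to 5522 at 32 °C, 2608 to 5824 at 34 °C, 0 to 760 for 32 °C against 28 °C, 4580 to 7091 for 34 °C against 28 °C and 104 to 3033 for 34 °C against 32 °C. Signal over background limits what dim probes can show, and the Cy3 channel of the 32 °C replicate 3 array was the dimmest.

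Median centring shifted the median of all probes by 0.17 for 32 °C against 28 °C, from 0.027 to 0.19. Probes higher and lower are given where the share of higher calls moved by over 10 percentage points, or 15 with an array left out. At 28 °C (reported 101 and 115) they were 52 and 142 with median centring, 43 and 21 with the authors' deposited values, 77 and 253 without the technical 32 °C against 28 °C array and 12 and 6 on slide 2. At 32 °C (reported 2168 and 1836) they were 2165 and 759 with median centring. At 34 °C (reported 1970 and 2456) they were 835 and 2265 with median centring. For 32 °C against 28 °C (reported 48 and 32) they were 0 and 1 with the scanner software's processed signals, 1371 and 1548 with no dye term, 625 and 704 with the 9 biological arrays, 16 and 36 with the authors' deposited values, 24 and 71 on slide 2 and 439 and 524 on slide 1. For 34 °C against 32 °C (reported 370 and 974) they were 16 and 977 with median centring, 2243 and 2189 with no dye term, 716 and 653 with the 9 biological arrays, 2085 and 2778 with a separate-channel model, 1930 and 2275 on slide 2 and 151 and 140 on slide 1.

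With an estimated correlation 0 lists passed in camera at any temperature (2, 11 and 4 at an unadjusted p under 0.05 at 28, 32 and 34 °C), and all 28 list calls were lost, as were all of those between heated temperatures. Fry gave 2, 17 and 16. At 28 °C lists numbered 7 with no dye term, 2 with the extracts apart, 2 with the deposited values, 8 on slide 2, 8 on slide 1, 2 with lists matched by gene symbols. At 32 °C they numbered 9 matched by gene symbols, and at 34 °C 5 with the extracts apart, 3 by gene symbols. Leaving out arrays gave 2 to 5, 14 to 15 and 4 to 10 lists at 28, 32 and 34 °C. The endoplasmic reticulum list at each temperature, and at 32 °C the heat shock, chaperonin, proteasome, antioxidant, ribosome biogenesis, respiratory, DNA replication and signalling lists, kept their calls in every setting they were tested in but the estimated correlation, as did heat shock at 34 °C. Lists were not tested in the separate-channel model, nor heat shock and chaperonin by gene symbols. The median of the heat shock list at 28 °C turned to -0.096 with median centring (adjusted p = 0.722), and the list reversed on slide 2 (median -0.0031, adjusted p = 0.693), and ribosomal proteins at 32 °C reversed with median centring (0.19, adjusted p = 0.23). Of 11, 8 and 4 list calls at 32 °C against 28 °C, 34 °C against 28 °C and 34 °C against 32 °C, 4, 0 and 2 were lost on the 9 biological arrays, 4, 0 and 2 on slide 1, 5, 4 and 1 on slide 2 and 6, 0 and 2 by fry. Between 28 and 32 °C ribosomal proteins reversed with median centring (0.48) and on slide 2 (-0.017). The cause was not tested.

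Correlations of fold changes are given with the value of simulated unchanged groups. For 28 and 32 °C they were 0.13 (simulated -0.52) with processed signals, 0.53 (simulated 0.24) without a dye term and -0.25 (simulated -0.86) with the extracts apart. For 28 and 34 °C they were 0.21 (simulated 0.21) without a dye term, 0.23 (simulated -0.00047) on the 9 biological arrays and 0.44 (simulated 0.86) with the extracts apart. For 32 and 34 °C they were 0.22 (simulated -0.51), 0.63 (simulated 0.21), 0.61 (simulated 0.0047) and 0.10 (simulated -0.83) with processed signals, no dye term, the 9 arrays and the extracts apart. Covariances exceeded the simulated ones in each of these except 28 and 34 °C with the extracts apart (-0.037). Differences among the controls passed for 1 probe without a dye term (adjusted p = 0.0377) and for 0 to 1 when arrays were left out, the fit without the technical 34 °C against 28 °C array giving no value.

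With an array left out, 94 of 560 values of called genes at 28 °C lost the call, over 23 genes. At 32 °C it was 39 of 1610 over 12 genes and at 34 °C 22 of 1582 over 13. None reversed. With the extracts apart 40 of 40, 88 of 115 and 45 of 113 called genes lost it at 28, 32 and 34 °C. On slide 2 alone the 28 °C values of HEXA (0.56), RBM3 (0.41), GTR8_RAT (0.12), H90B3 (-0.037) and VWA2 (0.11) reversed. At 34 °C there were reversals without a dye term for TBB1_CAEEL (0.036), on the 9 biological arrays for F16P2_BOVIN (0.32), PSA7 (0.13), RL20 (0.023) and TBB1_CAEEL (0.28), on slide 2 for F16P2_BOVIN (0.20) and TBB1_CAEEL (0.31) and on slide 1 for F16P2_BOVIN (0.28), PSA7 (0.093), RL20 (0.037) and TBB1_CAEEL (0.23). The cause was not tested.

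Replicate numbers were tested as a replicate block. Same-numbered arrays deviated together (r over 0.1) in 2 of 9 pairs (median -0.043), and some arrays matched another number best. Ratios cancel what both RNAs share, so pairing stays open. The replicate block gave 211, 3973 and 4373 probes at 28, 32 and 34 °C against 24 °C, and 77, 5671 and 1337 between heated temperatures. It changed no list call and ended 1 of 40 gene calls at 28 °C.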

Other observations

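Several lists held changed members in both directions and did not pass their tests. Among apoptosis genes at 32 °C, BIR52 (0.97 ± 0.15) was higher and CYC_CHLRE (-1.36 ± 0.21) lower. Of 61 members 6 rose, 11 fell and 16 passed adjusted over the list alone (adjusted p = 0.414). At 34 °C the adaptor TRAF2_MOUSE (1.20 ± 0.11) was higher and BI1_BOVIN (-2.01 ± 0.24), named after an inhibitor of cell death, lower. Of 61 members 11 rose, 15 fell and 26 passed adjusted over the list alone (adjusted p = 0.722). In lipid metabolism at 32 °C, ECHA_MOUSE (1.28 ± 0.16) of fatty acid oxidation was higher and ACSM3_RAT (-1.01 ± 0.14) lower. Of 107 members 18 rose, 13 fell and 31 passed adjusted over the list alone (adjusted p = 0.834), with a mean of 0.033 and a median of -0.0034 for a test directed up. The sterol carrier NPC2 (-1.87 ± 0.16) and the lipase LIPH (-1.42 ± 0.14) were lower at 34 °C. Of 107 members 15 rose, 18 fell and 33 passed adjusted over the list alone (adjusted p = 0.939), with a mean of -0.049 and a median of 0.023 for a test directed up. In glycolysis and gluconeogenesis, PCKGM (1.34 ± 0.15) was higher and the kinase PGK (-1.92 ± 0.24) lower at 32 °C. Of 38 members 13 rose, 6 fell and 20 passed adjusted over the list alone (adjusted p = 0.572). ENO (1.03 ± 0.12) was higher at 34 °C, and TPIS (-0.97 ± 0.10) was lower on 2 of 3 biological arrays. Of 38 members 6 rose, 12 fell and 18 passed adjusted over the list alone (adjusted p = 0.703). TPIS was well above background in 6 of 7 heated channels and 10 of 11 control channels.

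Cytoskeleton genes at 32 °C included the dynein chain DNAL1 (0.88 ± 0.087) and the actin-severing GELS1_LUMTE (-0.69 ± 0.10). Of 188 members 30 rose, 19 fell and 41 passed adjusted over the list alone (adjusted p = 0.813). At 34 °C GELS1_LUMTE (-1.52 ± 0.10) and the actin ACT1_ACACA (-2.57 ± 0.19) were lower. Of 188 members 21 rose, 39 fell and 60 passed adjusted over the list alone (adjusted p = 0.722). DNA repair included RD23B_HUMAN (0.90 ± 0.096) and APEX1 (1.17 ± 0.17) at 32 °C. Of 64 members 12 rose, 3 fell and 13 passed adjusted over the list alone (adjusted p = 0.404). It included UNG_FUSNN (-1.29 ± 0.19) and RD23B_HUMAN (-0.65 ± 0.099) at 34 °C. Of 64 members 13 rose, 8 fell and 21 passed adjusted over the list alone (adjusted p = 0.15). Channel and transporter genes had GLRA1 (-0.66 ± 0.099) and GRIK2 (-0.74 ± 0.12) lower at 32 °C. Of 116 members 6 rose, 16 fell and 16 passed adjusted over the list alone (adjusted p = 0.0897). The zinc transporter ZNT7 (1.31 ± 0.13) and ANO2 (0.67 ± 0.084) were higher at 34 °C. Of 116 members 9 rose, 27 fell and 34 passed adjusted over the list alone (adjusted p = 0.248). GLRA1 was well above background in 4 of 5 heated channels.

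Lists that passed at 32 °C but not at 34 °C still held changed members at 34 °C, and passing at 1 alone shows no difference. In the circadian list MTR1L (-1.40 ± 0.11) and ASMT_Stylophora (-0.99 ± 0.099) were lower. Of 17 members 3 rose, 6 fell and 9 passed adjusted over the list alone (adjusted p = 0.42). In innate immunity LBP_BOVIN (-2.05 ± 0.21) and BPI (-1.47 ± 0.15) were lower. Of 75 members 7 rose, 20 fell and 27 passed adjusted over the list alone (adjusted p = 0.0524). Among antioxidants GSTM3 (-0.997 ± 0.089) was lower and the peroxidase PXDN_XENTR (1.56 ± 0.15) higher. Of 69 members 12 rose, 19 fell and 33 passed adjusted over the list alone (adjusted p = 0.448). The proteasome inhibitor PSMF1 (-0.93 ± 0.087) was lower and the core subunit PSB1_MOUSE (1.18 ± 0.13) higher. Of 143 members 22 rose, 17 fell and 37 passed adjusted over the list alone (adjusted p = 0.596), with a mean of 0.0095 and a median of -0.0071 for a test directed up. In degradation and translocation OST48_XENLA (0.74 ± 0.083) was higher and SSRA_PONAB (-0.77 ± 0.083) lower. Of 47 members 7 rose, 4 fell and 9 passed adjusted over the list alone (adjusted p = 0.471). In DNA replication ORC1_BOVIN (1.04 ± 0.10) was higher and the cyclin CCNB (-1.03 ± 0.14) lower. Of 103 members 12 rose, 8 fell and 18 passed adjusted over the list alone (adjusted p = 0.398).

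At 28 °C some list tests that did not pass were directed up while the mean or the median of the list was below 0. Mean and median were -0.0056 and 0.013 for degradation and translocation, -0.044 and -0.039 for apoptosis, -0.036 and 0.032 for respiration, 0.017 and -0.012 for matrix, -0.041 and 0.0065 for cytoskeleton and -0.031 and 0.042 for germ cells. The measured fluorescent protein, GFPL_ANEMA (2.68 ± 0.86, adjusted p = 0.0276), was higher at 34 °C. GFPL_ANEMA lost the call without the 32 °C replicate 1 array (adjusted p = 0.062), the technical 32 °C against 28 °C array (0.0507), the technical 34 °C against 28 °C array (0.153) and the technical 34 °C against 32 °C array (0.0948).

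Lists of cnidocyte and germ cell markers did not pass against 24 °C. Cnidocyte markers had TX60B (0.50 ± 0.090) and DKK3_CHICK (0.67 ± 0.20) higher at 32 °C. Of 5 members 2 rose, 0 fell and 2 passed adjusted over the list alone (adjusted p = 0.407). The toxins TX60A (-1.47 ± 0.46) and TX60B (-0.45 ± 0.094) were lower at 34 °C. Of 5 members 0 rose, 2 fell and 2 passed adjusted over the list alone (adjusted p = 0.248). Germ cell markers had TDRD1 (0.42 ± 0.12) and PIWL1_DANRE (0.53 ± 0.16) higher at 32 °C. Of 18 members 6 rose, 1 fell and 8 passed adjusted over the list alone (adjusted p = 0.572), with a mean of -0.0028 and a median of -0.00060 for a test directed up. At 34 °C MSH4 (0.83 ± 0.13) and TDRD1 (0.72 ± 0.13) were higher. Of 18 members 3 rose, 2 fell and 5 passed adjusted over the list alone (adjusted p = 0.901), with a mean of -0.16 and a median of -0.041 for a test directed up. DKK3_CHICK was well above background in 8 of 11 control channels. TX60A was well above background in 5 of 7 heated channels and TX60B in 3 of 7 heated channels and 10 of 11 control channels. At 32 °C, DKK3_CHICK, PIWL1_DANRE and TDRD1 lost their calls without the technical 34 °C against 28 °C array (adjusted p = 0.113 to 0.156). So did DKK3_CHICK and PIWL1_DANRE without the technical 34 °C against 32 °C array (adjusted p = 0.0748 to 0.0898), and DKK3_CHICK without the technical 32 °C against 28 °C array (0.0926). At 34 °C, TX60A and TX60B lost their calls without the technical 34 °C against 28 °C array (adjusted p = 0.0737 to 0.12). So did TX60A without the 32 °C replicate 2 array (adjusted p = 0.0521), the technical 32 °C against 28 °C array (0.0605) and the technical 34 °C against 32 °C array (0.108).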
